A study of Escherichia coli with 16 samples.

How the data were processed

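RNA abundance was measured in Escherichia coli cultures on 16 membrane gene arrays that carry the annotated open reading frames. Per the labels, RNA was reverse transcribed into radiolabelled cDNA with gene-specific primers, and mitomycin C (MMC), a drug that crosslinks DNA, was added to growing cultures. The arrays belong to 8 experiments of 1 before and 1 after array each. The groups were unexposed cultures (2 experiments), sustained growth in MMC (3 experiments) and a 10 min pulse of MMC followed by further growth (2 experiments). The eighth experiment, sustained 1b, compares 25 min with 10 min in MMC, so its reference is already exposed. It was kept out of the main comparisons. Beyond the experiment codes, nothing in the labels says that experiments were separate cultures, so p-values measure only the spread between these experiments, which may in part be technical.

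The deposited values are intensities on a linear scale, 1 per probe, for 4290 probes. The scanner, the image analysis, any background subtraction and the averaging of spots are not given in the sources used here. No between-array normalization is visible in the deposited intensity values, whose medians ran from 22739 to 187200. Each array has 1 repeated lowest value, between 3335 and 20160, which 17 to 616 probes share (0.396% to 14.4% of the array). A gene at that value on every array of one side of a comparison has only a bound there, taken against the lowest other value of the array. The median intensity was 4.87 to 31.7 times the lowest value. The number of arrays limits the precision.

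Probes were named through the platform annotation, with symbols from the RefSeq table of assembly ASM584v2. Of the 4290 probes, 4185 had 1 gene symbol, 105 had none and 0 had several; 7 were named from the platform annotation only, and 87 probes carry a symbol that is on more than 1 probe. The genome build behind the array design is not given in the sources used here, so no coordinates are printed. The annotation was checked on the values: changes of chromosomal neighbours correlated at 0.152 to 0.421 across 4094 pairs in the 8 experiments, against -0.0365 to 0.0150 for shuffled probes.

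The treatment of values was fixed before the data were examined. Arrays were quantile normalized over all 16 arrays because their medians differed by more than the preset tolerance, and log2 was taken. No value was at or below 0, so no floor was set. The change in each experiment was log2 after minus log2 before, which makes the experiment the block. This design follows the labels, which describe a comparison of levels after and before damage in each experiment. Experiment codes were checked as pairs: within groups, deviations of the before and after array of one experiment from the group means correlated above 0, at 0.609 to 0.739 in the sustained group, 0.619 in the pulse group and 0.975 in the unexposed group. In groups of 2 experiments centring makes the values for arrays of different experiments the negative of these, and in the sustained group, where they ran from -0.610 to 0.110, it also pulls them below 0, so they are no separate check.

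Changes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment and a threshold of 0.05. A fit with 3 group means over 7 experiments had 4 residual degrees of freedom. It gave the change in each group and the differences between groups. A second fit with all 5 exposed experiments as 1 group had 5 residual degrees of freedom. Errors after ± are standard errors from these fits unless SD is written. All 4290 probes were tested, each on its own, so that counts of genes are counts of probes. Experiments in a group differ in time, and the pulse experiments also in the labelled dose, so the spread includes those differences.

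The genes named were set by rule before the data were examined. They are the 12 highest and 12 lowest changes past the threshold with the same sign in every experiment of the group, up to 4 members of each list past the test or otherwise its 2 largest changes, and 13 SOS genes whatever their test. Genes outside the rule are marked where they are named. The 27 gene lists were written beforehand as well. They cover the SOS regulon, cryptic prophages, stress responses, translation, central metabolism, replication, division, repair, nucleotide and amino acid synthesis, iron uptake and toxin-antitoxin pairs. Of 607 list entries, 596 matched a probe. In 4 lists a gene is on more than 1 probe, so that the SOS list has 34 probes of 32 genes, the Rac list 27 of 26, the list of the prophage that carries alpA 25 of 23, and branched-chain amino acid synthesis 15 of 14. Lists were tested with camera (of limma) at a preset inter-gene correlation of 0.01 and again with the correlation estimated, and with fry. Camera adjusted p-values run over the 27 lists of a comparison.

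The limma step was tested on simulated data with 4290 genes, of which 200 were changed in each of 5 simulations. For sustained MMC, 93.4% of genes changed 2-fold were recovered, and 85.4% for the pulse, 97.0% for all MMC, 61.2% for sustained minus unexposed and 46.9% for pulse minus unexposed. For genes changed 4-fold, recovery in these comparisons was between 95.5% and 100%. Between 4.81% and 5.96% of calls were false. Noise was drawn independently for each gene, and a changed gene got the same shift in every exposed experiment. Array clusters, differences in time or dose and correlation between genes were not simulated. The rates hold for that setting only and are no estimate of those in the real data.

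Alternatives were median scaling, no normalization, cyclic loess within each experiment, an offset of 35914 (the 25th percentile of normalized values), the dimmest 25% of genes left out, no replicate block, sustained 1b added, a trended and robust variance model, an ordinary test per gene without moderation, and each experiment left out in turn. Alternatives added after seeing the data were genes at an array's lowest value left out, list tests without the block, list tests with 1 value per gene, the array cluster as a term, and a variance trend on mean intensity. Array clusters were found from the before arrays with ribosomal protein genes left out, by average-linkage clustering with a fixed number of clusters. Figures were drawn with matplotlib 3.10.9.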

Results

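Transcript levels of 4290 E. coli probes were compared before and after exposure to mitomycin C (MMC), to see how gene expression changes after DNA damage. Unexposed cultures were sampled at 0 min and again at 40 min (unexposed 1) or 80 min (unexposed 2). Cultures in 0.3 µg/ml MMC were sampled at 0 min and at 25 min (sustained 1a), 40 min (sustained 2) or 80 min (sustained 3). Pulse 1 was exposed for 10 min to MMC labelled 3.0 µg/ml and then grown for 50 min, and pulse 2 was exposed for 10 min to 0.3 µg/ml and then grown for 70 min. Each experiment had 1 before and 1 after array, and 14 arrays entered the comparisons.

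The before and after arrays of an experiment correlated at 0.942 to 0.986 across genes. Arrays of different experiments correlated at 0.860 to 0.988, except those of unexposed 2, which reached only 0.607 to 0.651 with any other experiment. Genes are not independent replicates in these correlations. Among the before arrays, those of unexposed 1, sustained 1a and sustained 3 correlated at 0.958 to 0.988 with one another (cluster A). Those of sustained 1b, sustained 2, pulse 1 and pulse 2 correlated at 0.915 to 0.970 (cluster B), and arrays of A with those of B at 0.885 to 0.948. Unexposed 2 stood alone. Sustained 1b lay between the clusters, at 0.934 to 0.948 with the arrays of A and 0.915 to 0.966 with the others of B.

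Changes are given after quantile normalization. With no normalization the median change of all genes moved to -3.00 in sustained 3 and 1.86 in pulse 1, and list medians followed it. In that setting the SOS, TCA cycle, NADH dehydrogenase I and oxidative stress medians of sustained MMC turned to -0.97, -0.09, -0.66 and -0.93. The ATP synthase, chromosome replication, cell division and aminoacyl-tRNA synthetase medians of the pulse turned to 0.34, 0.51, 0.45 and 0.18, and the oxidative stress and RpoS medians of all exposed experiments to -0.17 and -0.22. Camera, which sets a list against the other genes, gave the same direction for each of these lists, but its calls for ATP synthase, chromosome replication and cell division in the pulse ended (adjusted p = 0.146, 0.0631 and 0.121).

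**Figure D1:**
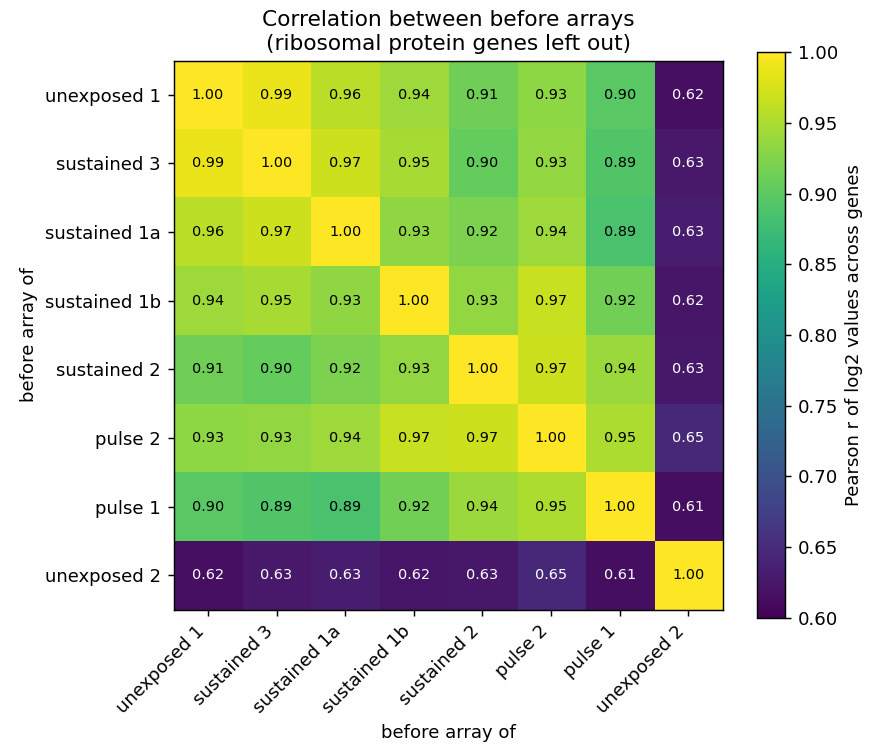
Pearson correlation across genes of log2 deposited values, not normalized, between the before arrays of the 8 experiments, with ribosomal protein genes left out. Unexposed 2 correlates at 0.65 or less with every other before array, and the remaining arrays form 2 overlapping clusters.

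In unexposed cultures no gene passed the test, but genes of central metabolism had the largest list shifts. The TCA cycle list, the enzymes that oxidize acetyl-CoA, had a median change of 0.94 on the log2 scale over 16 genes, with medians of 0.46 in unexposed 1 and 1.34 in unexposed 2. For gltA, citrate synthase, the change was 2.67 ± 0.858 (n = 2; limma adjusted p = 0.716). NADH dehydrogenase I, the proton-pumping entry of the respiratory chain, had a median of 0.49 over 13 genes, and the 54 ribosomal protein genes one of -0.28. The SOS regulon, the DNA damage genes repressed by LexA, had a median of 0.03 over 34 probes of 32 genes. Changes of recN and recA were -0.11 and 0.10 in unexposed 1 and 0.00 and -0.16 in unexposed 2. For sulA the change was -0.16 in unexposed 2 and at least 0.19 in unexposed 1, where it was at the lowest array value before (0.63 as measured from that value).

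By limma, 0 of 4290 genes passed in the unexposed experiments (257 at an unadjusted p under 0.05, smallest adjusted p = 0.153; 0 with the unmoderated test), and 0 of the 16 TCA cycle genes passed over all genes or adjusted over the list alone. Camera put the TCA cycle and NADH dehydrogenase I lists above other genes (adjusted p = 1.37e-08 and 1.83e-08) and the ribosomal list below them (adjusted p = 6.03e-05). With an estimated correlation these became adjusted p = 0.622, adjusted p = 0.622 and adjusted p = 0.798, and no list passed. Camera also called the oxidative stress list higher (median 0.20, adjusted p = 0.013) and the chromosome replication, cell division and heat shock lists lower (medians -0.12, -0.13 and -0.083, adjusted p = 0.00113, 0.0031 and 0.033). With an estimated correlation these had adjusted p = 0.622, adjusted p = 0.554, adjusted p = 0.554 and adjusted p = 0.694. Without unexposed 2 these 4 calls ended (adjusted p = 0.0581, 0.245, 0.245 and 0.245). Without unexposed 1 the oxidative stress call ended (median 0.07, adjusted p = 0.183) and the cell division median was -0.26. The heat shock call also ended under median scaling, with no normalization and without the block (adjusted p = 0.0662, 0.312 and 0.113), and the oxidative stress median was 0.07 with the offset or without the dimmest 25% of genes. Without unexposed 2, whose arrays stand apart, the count of genes was 1, the TCA cycle median was 0.46, and the TCA cycle and ribosomal calls ended (adjusted p = 0.0794 and 0.0706).

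In sustained MMC the SOS genes sulA, recN and recA had higher values after exposure in 3 of 3 experiments, although none passed the test over all genes. The change of sulA (b0958), which encodes an inhibitor of cell division, was 2.05 ± 0.330 on the log2 scale or 4.13-fold (n = 3; limma adjusted p = 0.0637). For recN (b2616), a recombination repair protein, it was 1.43 ± 0.243 or 2.70-fold (limma adjusted p = 0.0771), and for recA (b2699), the recombinase that triggers LexA cleavage, 1.26 ± 0.219 or 2.40-fold (limma adjusted p = 0.0790). The values of sulA were 0.997 at 25 min, 2.22 at 40 min and 2.92 at 80 min, each in a different experiment. The genes that fell were fecB (b4290), the periplasmic binding protein for ferric citrate, by 1.59 ± 0.136, nsrR, a nitric oxide-sensing repressor, by 1.59 ± 0.186, and rimP, a ribosome maturation factor, by 1.12 ± 0.132 (limma adjusted p = 0.0128, 0.0490 and 0.0490). Each fell in 3 of 3 experiments, and values in unexposed 1 and 2 were -0.92 and -1.03 for fecB and -1.35 and -0.95 for rimP. For nsrR, at the lowest value on 1 of 3 after arrays, the value was -0.60 in unexposed 2, and in unexposed 1, at the lowest value after, it was -1.14 or lower.

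The 34 SOS probes had a median change of 0.16, or 0.18 with 1 value for each of their 32 genes, since yehH is on 3 probes. None passed over all genes, and 4 were higher and 1 lower adjusted over the list alone. Camera placed the list above other genes (adjusted p = 0.00942), a call lost at adjusted p = 0.353 with an estimated correlation and at adjusted p = 0.104 without sustained 3. The median was 0.08 with the offset and 0.11 with sustained 1b added. The other SOS genes had small values: uvrB 0.42, uvrA 0.39, ruvA 0.36, dinI 0.31, yebG 0.22, ssb 0.16, umuC 0.12, lexA -0.05, uvrD -0.12 and umuD -0.29. After exposure umuD was at the array's lowest value on 2 of 3 arrays, and dinI was at it on 1 of 3 arrays before and 1 of 3 after.

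**Figure D2:**
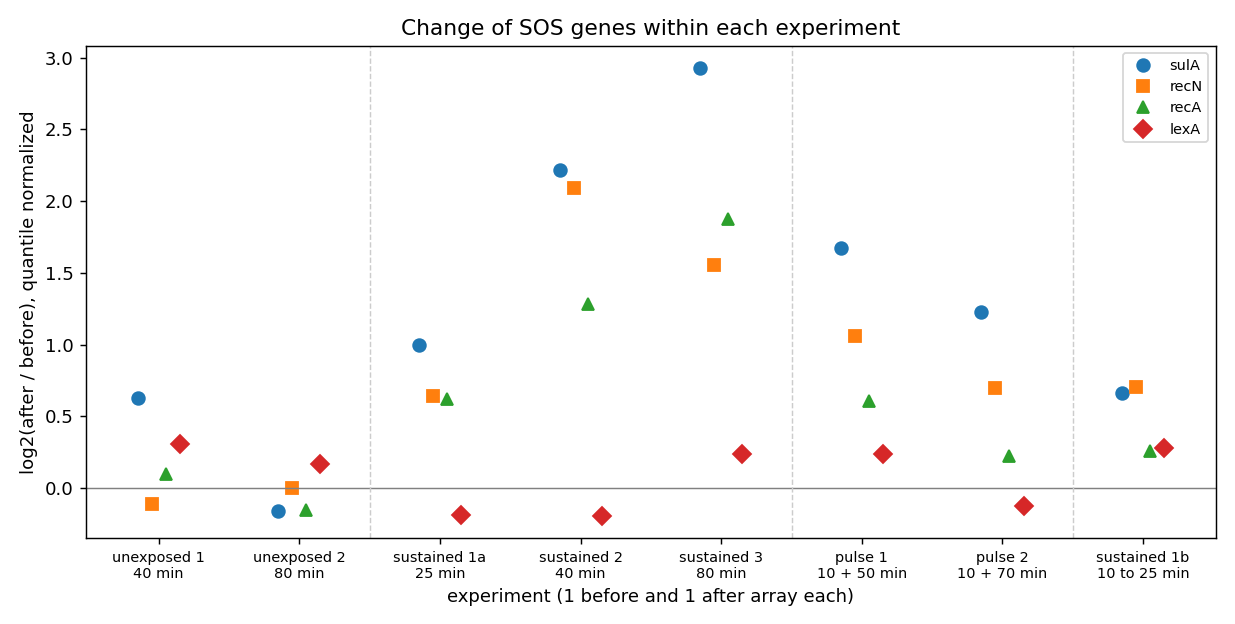
Change of sulA, recN, recA and lexA within each experiment, as log2 of the after over the before array (vertical axis), for the 8 experiments on the horizontal axis, 1 point per gene and experiment. The change of sulA lies between 0.997 and 2.92 in sustained 1a, 2 and 3, at 0.66 in sustained 1b (10 to 25 min of MMC), at 0.63 in unexposed 1, where it starts from the array's lowest value, and at -0.16 in unexposed 2, while lexA stays between -0.19 and 0.31.

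The TCA cycle list had a median of 1.08 in sustained MMC, with 12 of 16 genes higher adjusted over the list alone and 0 over all genes. Values were 2.39 ± 0.511 for sucD, a succinyl-CoA synthetase subunit, and 2.08 ± 0.360 for sdhB, the iron-sulfur subunit of succinate dehydrogenase. NADH dehydrogenase I had a median of 0.50, with 11 of 13 genes higher adjusted over the list alone and 0 over all genes. Oxidative stress genes had 6 of 21 higher adjusted over the list alone and a median of 0.22, with ahpC, the peroxide-reducing subunit of alkyl hydroperoxide reductase, at 0.89. In unexposed cultures the oxidative stress median was 0.20, and the values of ahpC were 0.44 and 0.35. Iron uptake genes had 1 of 34 lower over all genes, 6 lower adjusted over the list alone, and a median of -0.39, with medians of -0.30, -1.01 and 0.004 in sustained 1a, 2 and 3. The ribosomal list had a median of -0.92, with 0 of 54 passing over all genes or adjusted over the list alone. Its median was -2.05 in sustained 2 but -0.32 and -0.30 in sustained 1a and 3.

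Camera called the TCA cycle, NADH dehydrogenase I and oxidative stress lists higher (adjusted p = 7.41e-11, 8.37e-09 and 8.02e-06), each at adjusted p = 0.353 with an estimated correlation. It called ribosomal and iron uptake genes lower (adjusted p = 8.24e-20 and 8.19e-09), at adjusted p = 0.362 and adjusted p = 0.353 with an estimated correlation. Without sustained 2 the iron uptake, ribosomal, TCA cycle and NADH dehydrogenase I medians were -0.10, -0.33, 0.69 and 0.33, and without sustained 3 the iron uptake median was -0.64. With the offset it was -0.23. In all, limma passed 0 higher and 3 lower genes of 4290 (628 at an unadjusted p under 0.05). The count was 0 with no normalization, without the experiment block, with the offset, with the trended variance, with the unmoderated test, without sustained 2, or without either pulse experiment, and 26 without sustained 1a, 1 without sustained 3, and 11 with the variance trend on mean intensity. It was also 11 with sustained 1b added as a further experiment, which is no new replicate if sustained 1a and 1b came from the same culture.

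After the MMC pulse treB and treC, for trehalose uptake and cleavage, were among the 12 genes named as highest and rose by 2.95 ± 0.336 and 2.43 ± 0.328 on the log2 scale (n = 2; limma adjusted p = 0.00567 and 0.00943). The maltose-binding protein gene malE rose by 2.79 ± 0.485, and mglB and mglC of the galactose transporter by 2.13 ± 0.239 and 2.42 ± 0.319. Both mglA, the ATPase of that transporter, and tnaB, a tryptophan permease, were at the lowest array value on 2 of 2 before arrays, so that mglA rose at least 5.48-fold and tnaB at least 9.22-fold. For mglC this held on 1 of 2 before arrays. The lactate permease gene lldP, the ribosome hibernation factor gene raiA, and gcvH, aldA and dadA rose as well, the first 4 of them by 3.35, 3.08, 2.54 and 2.49. Values in unexposed 1 and 2 were 1.88 and 2.44 for treB, 1.61 and 1.57 for raiA, and 1.65 and 2.64 for gcvH.

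Among the 12 genes named as lowest, the change in the pulse was -2.27 ± 0.189 for cspA, a cold shock protein gene (limma adjusted p = 0.00271), -3.03 ± 0.228 for nsrR (limma adjusted p = 0.00271), -2.45 ± 0.438 for obgE, a GTPase of ribosome assembly, and -2.31 ± 0.523 for fis, a nucleoid protein of fast growth. For cspG and suhB, at the lowest value on 2 of 2 after arrays, the fall was at least 4.21-fold and 4.12-fold. Values were -2.25 for rsfS, -2.21 for aceE, -2.21 for cspF and -2.16 for pdhR, with rsfS and cspF at the lowest value on 1 of 2 after arrays. In unexposed 1 and 2 they were -1.18 and -1.41 for cspA and -1.02 and -0.97 for fis.

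Of 54 ribosomal protein genes, 16 were lower after the pulse over all genes and 49 adjusted over the list alone, with a median of -1.44 (camera adjusted p = 1.17e-20, and adjusted p = 0.683 with an estimated correlation). The largest were rplJ at -2.31 ± 0.451, rplI at -2.27 ± 0.539 and rpsT at -2.09 ± 0.300. Aminoacyl-tRNA synthetases, which charge tRNAs, had 5 of 23 lower over all genes and 14 adjusted over the list alone, with thrS at -1.13 and pheT at -1.04. Of 9 ATP synthase genes, 2 were lower over all genes and 3 adjusted over the list alone, with atpI at -0.97 and atpB at -0.75. Chromosome replication genes had 4 of 30 lower over all genes and 6 adjusted over the list alone, with dnaE, the catalytic subunit of DNA polymerase III, at -1.72 and at the lowest value on 1 of 2 after arrays. Cell division genes had 3 of 21 lower over all genes, and 7 lower and 1 higher adjusted over the list alone, with zapA at -1.93. In unexposed 1 and 2 the values were -0.78 and -1.13 for dnaE and -1.10 and -0.33 for zapA, and the replication and division medians over both were -0.12 and -0.13. The TCA cycle list had 1 of 16 higher over all genes (sdhA, 1.34) and 8 adjusted over the list alone. Of 31 RpoS general stress genes 3 were higher over all genes and 4 adjusted over the list alone, with katE, a stationary phase catalase, at 1.35 and at the lowest value on 1 of 2 before arrays.

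Among SOS genes the pulse gave 2 higher and 1 lower of 34 probes over all genes, and 3 higher and 2 lower adjusted over the list alone. The SOS genes yebG and cho rose by 0.62 and 0.61 (limma adjusted p = 0.0442 and 0.0431), and ybfE, at the lowest value on 2 of 2 after arrays, fell at least 1.78-fold. Values for sulA, recN and recA were 1.45 ± 0.404, 0.88 ± 0.297 and 0.42 ± 0.268, which did not pass (limma adjusted p = 0.0639, 0.106 and 0.330), with sulA at the lowest value on 1 of 2 before arrays.

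By limma 141 genes rose and 238 fell after the pulse, 379 of 4290 (1200 at an unadjusted p under 0.05). Camera called lower the ribosomal list and the aminoacyl-tRNA synthetases (for the latter, adjusted p = 2.57e-05, and adjusted p = 0.683 with an estimated correlation). It called lower ATP synthase and chromosome replication too (adjusted p = 0.00626 for each list, and adjusted p = 0.683 with an estimated correlation), and called higher the TCA cycle (adjusted p = 0.000401, and adjusted p = 0.685 with an estimated correlation). Cell division was also called lower (median -0.26, adjusted p = 0.0164), a call that ended under median scaling (adjusted p = 0.0562). Without pulse 1 the division call ended too, at a median of -0.15. NADH dehydrogenase I was called higher (median 0.44, adjusted p = 0.00847), against a median of 0.49 in unexposed cultures. That call also ended without pulse 1, at a median of 0.46. The ATP synthase call ended without pulse 1 (adjusted p = 0.107) and with no normalization (adjusted p = 0.146), the replication call with no normalization (adjusted p = 0.0631), and the TCA cycle call without pulse 2 (adjusted p = 0.113). Without pulse 1 the replication median was -0.10, against -0.16 under median scaling and -0.14 with the offset, and the TCA cycle median 1.57, and without pulse 2 the ribosomal median was -0.96. For the pulse MMC change the count was 606 under median scaling (342 higher, 264 lower) and 584 without sustained 2, but 116 without either unexposed experiment, 30 without pulse 2, 0 without pulse 1, 1 with no normalization, 1 with the trended variance, 2 with the unmoderated test and 0 without the block. Both pulse experiments lie in array cluster B.

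Across all 5 exposed experiments sulA rose by 1.81 ± 0.258 on the log2 scale or 3.50-fold (SD 0.779, n = 5; limma adjusted p = 0.0102), recN by 1.21 ± 0.199 (limma adjusted p = 0.0150) and recA by 0.92 ± 0.211 (limma adjusted p = 0.0305). Each was higher in 5 of 5 experiments, and sulA was at the lowest value on 1 of 5 before arrays. The SOS list had 4 of 34 probes higher and 2 lower over all genes, 7 higher and 2 lower adjusted over the list alone, and a median of 0.20 (camera adjusted p = 0.0931). Values for dinI, ruvA and yebG were 0.32, 0.32 and 0.38 (limma adjusted p = 0.0613, 0.0613 and 0.0619), and for lexA -0.01 (limma adjusted p = 0.970).

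TCA cycle genes rose in the exposed experiments, 11 of 16 over all genes and 14 adjusted over the list alone, with a median of 1.08. Among them sucD rose by 2.19 ± 0.377, gltA by 2.10 ± 0.505, sucA by 1.97 ± 0.374 and sdhB by 1.88 ± 0.273 (limma adjusted p = 0.0160, 0.0352, 0.0205 and 0.0107). In unexposed 1 and 2 the values were 0.52 and 2.65 for sucD and 1.27 and 4.08 for gltA. NADH dehydrogenase I had 7 of 13 higher over all genes and 11 adjusted over the list alone, led by nuoK at 1.20 and nuoM at 0.90. Oxidative stress genes had 5 of 21 higher over all genes and 7 adjusted over the list alone, with the catalase gene katG at 0.82 and the superoxide dismutase gene sodB at 0.70. In unexposed 1 and 2 these were 0.39 and 0.07 for katG and 0.43 and 0.61 for sodB, and the oxidative stress median over both was 0.20. RpoS general stress genes had 3 of 31 higher over all genes and 4 adjusted over the list alone, with katE at 1.16 and at the lowest value on 1 of 5 before arrays. Outside the lists, raiA rose by 2.46 and malE by 2.14, and in unexposed 1 and 2 the values of malE were 1.43 and 0.83.

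Ribosomal protein genes fell, 45 of 54 over all genes and 51 adjusted over the list alone, with a median of -1.19 and with rplJ at -1.63 ± 0.324. Iron uptake genes had 5 of 34 lower and 1 higher over all genes, and 9 lower and 1 higher adjusted over the list alone. Among those that fell, fecB, fecA and fecD belong to ferric citrate transport, with fecB at -1.75 ± 0.120 (limma adjusted p = 0.000555), fecA at -1.48 and fecD at -1.19. Aminoacyl-tRNA synthetases had 7 of 23 lower and 1 higher over all genes, and 13 lower and 1 higher adjusted over the list alone, with trpS at -0.94 and lysU at 0.71. Chromosome replication had 4 of 30 lower over all genes and 7 adjusted over the list alone, with dnaE at -1.15 and at the lowest value on 1 of 5 after arrays. Cell division had 4 of 21 lower over all genes and 8 adjusted over the list alone, with zapA, which bundles FtsZ filaments, at -1.54 and at the lowest value on 1 of 5 after arrays. In unexposed 1 and 2 the values were -0.78 and -1.13 for dnaE and -1.10 and -0.33 for zapA, and camera called both lists lower there too (medians -0.12 and -0.13, adjusted p = 0.00113 and 0.0031). Those unexposed calls had adjusted p = 0.554 for each list with an estimated correlation and ended without unexposed 2 (adjusted p = 0.245 for each list). Pyrimidine synthesis had 2 of 10 lower over all genes, and 3 lower and 1 higher adjusted over the list alone, with pyrH at -1.04.

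**Figure D3:**
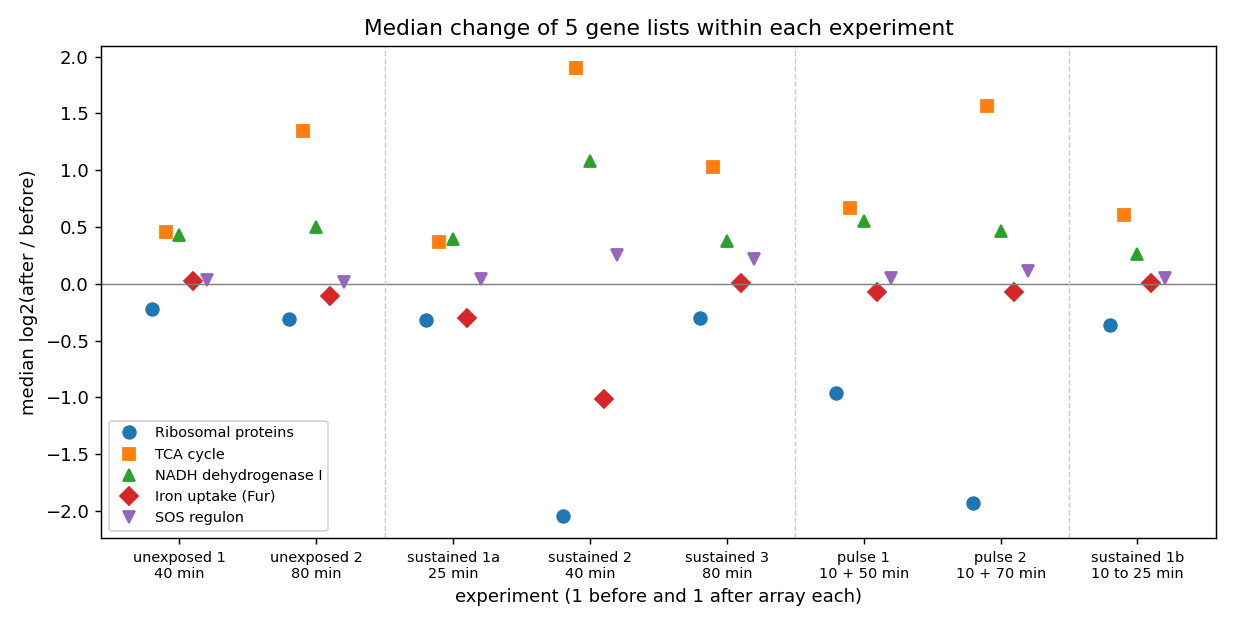
Median log2 change (after over before array, vertical axis) of the 54 ribosomal protein, 16 TCA cycle, 13 NADH dehydrogenase I, 34 iron uptake and 34 SOS probes in each of the 8 experiments (horizontal axis), 1 point per list and experiment. The ribosomal median is -2.05 in sustained 2, -0.96 in pulse 1 and -1.93 in pulse 2, and between -0.37 and -0.22 in the other experiments; the TCA cycle median is above 0 in all 8.

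The remaining lists had few calls over all exposed experiments. Over all genes, 1 of 9 ATP synthase, 3 of 53 flagella, 2 of 9 arginine, 1 of 10 methionine, 1 of 5 tryptophan, 1 of 20 heat shock and 1 of 21 base excision and mismatch repair genes passed, as did 3 of 34 Qin and 1 of 22 DLP12 prophage genes and 1 of 25 probes (23 genes) of the cryptic prophage that carries alpA. Adjusted over the list alone the counts were 1, 0, 3, 1, 1, 1, 1, 1, 0 and 0 in the same order. None passed either way in the e14 and Rac prophage lists (20 and 27 probes), purine (16), histidine (8) or branched-chain amino acid synthesis (15), or toxin-antitoxin pairs (18).

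By limma 176 genes were higher and 293 lower in the exposed experiments, 469 of 4290 (1286 at an unadjusted p under 0.05). Camera called the TCA cycle list higher (adjusted p = 7.20e-09) and the ribosomal list lower (adjusted p = 2.42e-25), each at adjusted p = 0.321 with an estimated correlation. NADH dehydrogenase I, oxidative stress and RpoS lists were called higher (adjusted p = 2.68e-06, 0.00193 and 0.0161), at adjusted p = 0.321, adjusted p = 0.321 and adjusted p = 0.329 with an estimated correlation. Called lower were iron uptake and aminoacyl-tRNA synthetases (adjusted p = 2.93e-05 for each list), at adjusted p = 0.422 and adjusted p = 0.321 with an estimated correlation, and replication, division and ATP synthase (adjusted p = 0.0142, 0.0142 and 0.0161), at adjusted p = 0.321, adjusted p = 0.321 and adjusted p = 0.513 with an estimated correlation. With no normalization the replication, division and ATP synthase calls ended (adjusted p = 0.0751, 0.0751 and 0.141). They also ended without pulse 1 (adjusted p = 0.0557, 0.0533 and 0.0829), and ATP synthase without sustained 2 (adjusted p = 0.0595). The RpoS call ended with the offset (adjusted p = 0.0576), without the dimmest 25% of genes (adjusted p = 0.591, and replication at adjusted p = 0.0995) and without sustained 2 (adjusted p = 0.0595), where the iron uptake median was -0.13 and that of replication -0.18. With the offset the oxidative stress and replication medians were 0.16 and -0.07. Without the block the SOS list was called higher (adjusted p = 0.0495). For the all MMC change the count was 153 without sustained 2, 52 without pulse 1, 33 without pulse 2, 190 without either unexposed experiment, 1 with no normalization, and 0 without the block, with the trended variance or with the unmoderated test. Within array cluster B (sustained 2, pulse 1 and pulse 2) 659 genes passed, and within cluster A (sustained 1a and 3) 0 passed (281 at an unadjusted p under 0.05).

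Set against unexposed cultures, the changes of sulA, recN and recA in sustained MMC were larger by 1.81 ± 0.521, 1.48 ± 0.384 and 1.29 ± 0.346 on the log2 scale, differences that did not pass (limma adjusted p = 0.999 for each gene), with sulA at the lowest value on 1 of 2 unexposed before arrays. The SOS list differed by a median of 0.19, with 0 of 34 probes passing over all genes or adjusted over the list alone. Iron uptake differed by -0.37, ribosomal genes by -0.53, heat shock genes, the chaperones and proteases of the RpoH regulon, by 0.20, and the TCA cycle by 0.34. No iron uptake, ribosomal, heat shock or TCA cycle gene passed over all genes or adjusted over the list alone.

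Camera called the SOS and heat shock differences higher (adjusted p = 0.00115 and 0.00206) and the iron uptake and ribosomal differences lower (adjusted p = 5.75e-09 and 1.19e-08), at adjusted p = 0.616, adjusted p = 0.616, adjusted p = 0.616 and adjusted p = 0.647 with an estimated correlation. Called lower too were ATP synthase (-0.41), aminoacyl-tRNA synthetases (-0.20) and tryptophan synthesis (-0.13), at adjusted p = 0.0328 for each list. Oxidative stress and RpoS were called higher (0.21 and 0.09, adjusted p = 0.0321 and 0.0417). The ATP synthase, synthetase, oxidative stress and RpoS calls ended without sustained 2 (adjusted p = 0.234, 0.157, 0.157 and 0.25). The tryptophan call ended without sustained 1a (adjusted p = 0.222). These calls hung on the unexposed experiments as well. Without unexposed 1 the synthetase and RpoS calls ended, at median differences of -0.002 and 0.02. The ATP synthase and oxidative stress calls ended without unexposed 2 (-0.26 and 0.18), and the tryptophan call without either one. The RpoS call also ended with loess, with the offset and without the dimmest 25% of genes (adjusted p = 0.0678, 0.116 and 0.605). Without sustained 2 the ribosomal call ended at a median difference of -0.06 (adjusted p = 0.911), and the iron uptake and SOS differences were -0.17 and 0.08. The ribosomal difference was -0.90 without sustained 1a, that of iron uptake -0.68 without sustained 3 and that of SOS 0.09 without unexposed 2. With the offset the SOS and iron uptake differences were 0.08 and -0.23, and with no normalization the SOS and heat shock medians turned to -0.86 and -0.84. In the latter setting camera still called both lists higher than other genes (adjusted p = 2.84e-05 and 0.00943). Camera did not call the TCA cycle difference (adjusted p = 0.078), which was -0.05 without unexposed 1 and 0.005 without sustained 2. It was called without unexposed 2 (0.77, adjusted p = 7.54e-06), without sustained 1a (0.68, adjusted p = 0.000338), without the block (adjusted p = 0.0193) and with no normalization, where its median turned to -0.70 (adjusted p = 0.00943). By limma 0 genes passed (78 at an unadjusted p under 0.05), and 0 with the unmoderated test (140 at an unadjusted p under 0.05). Both counts are below the share of 0.05 of all genes that chance would give, so they are no sign of a difference. Within cluster A the differences were at most 1.77 for sulA, at the lowest value before in unexposed 1 (1.33 as measured from it), 1.21 for recN, 1.15 for recA, 0.08 for the SOS median and -0.12 for the ribosomal median, from sustained 1a and 3 against unexposed 1 alone. The iron uptake, heat shock and TCA cycle medians there were -0.15, 0.13 and 0.48. Fitted with the cluster as a term, or without unexposed 2, 1 gene passed.

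Changes after the pulse minus those in unexposed cultures had a median of -1.17 over the ribosomal list, -0.60 over ATP synthase, -0.52 over aminoacyl-tRNA synthetases and 0.17 over the SOS list. No gene of the ribosomal, ATP synthase, aminoacyl-tRNA synthetase or SOS lists passed over all genes or adjusted over the list alone. Camera called the first 3 lower (adjusted p = 1.90e-17, 8.50e-05 and 1.69e-05), each at adjusted p = 0.776 with an estimated correlation. With no normalization the ATP synthase and aminoacyl-tRNA synthetase medians turned to 0.30 and 0.33, though camera still called both lists lower (adjusted p = 0.0025 and 7.31e-05). Without pulse 2 the ribosomal median was -0.78. By limma 0 genes passed (389 at an unadjusted p under 0.05; smallest adjusted p = 0.135), and 0 with the unmoderated test. No cluster holds both groups. With the cluster as a term the ribosomal median turned to 0.51, the ATP synthase median to 0.03 and the SOS median to -0.004. That of aminoacyl-tRNA synthetases went to -0.10. This fit left out unexposed 2, and only the sustained group has experiments in both clusters. Its cluster term is thus the difference of sustained 2 from sustained 1a and 3, which holds the larger ribosomal fall of sustained 2. These moves therefore decide nothing about the array cluster. Under either variance trend 1 gene passed.

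Sustained minus pulse changes were 0.84 ± 0.346 for recA, 0.60 ± 0.521 for sulA and 0.56 ± 0.384 for recN, and none passed (limma adjusted p = 0.591, 0.725 and 0.670), with sulA at the lowest value on 1 of 2 pulse before arrays. The ribosomal median difference was 0.46, that of aminoacyl-tRNA synthetases 0.31 and that of heat shock genes 0.23, with 0 genes passing over all genes or adjusted over the list alone. Camera called these 3 higher (adjusted p = 4.14e-07, 0.00234 and 0.00234), each at adjusted p = 0.728 with an estimated correlation, and under median scaling the last 2 ended (adjusted p = 0.0508 for each list). ATP synthase (0.22), chromosome replication (0.14) and branched-chain amino acid synthesis (0.27) were called higher as well (adjusted p = 0.022, 0.0236 and 0.0296). These further calls ended with no normalization and under median scaling (for the latter, adjusted p = 0.18, 0.0508 and 0.0988). Without pulse 2 the ribosomal and synthetase calls ended (adjusted p = 0.0977 and 0.335), and without pulse 1 the heat shock call (adjusted p = 0.229). The ribosomal difference ran from 0.10 without pulse 2 to 1.09 without sustained 2, that of synthetases was 0.083 without pulse 2 and 0.20 without sustained 3, that of heat shock 0.15 without pulse 1, and with no normalization the 3 medians turned to -1.52, -1.58 and -1.66 and the synthetase and heat shock calls ended (adjusted p = 0.0809 and 0.0619). By limma 0 genes passed (347 at an unadjusted p under 0.05; smallest adjusted p = 0.235), and 0 with the unmoderated test. Within cluster B, sustained 2 against both pulse experiments, the ribosomal difference turned to -0.66, and it was 0.87 for recA, 1.22 for recN and at most 1.08 for sulA, at the lowest value before in pulse 1 (0.77 as measured from it).

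Across genes, mean changes in sustained MMC correlated at 0.599 with those in unexposed cultures and at 0.724 with those after the pulse, and changes after the pulse at 0.612 with the unexposed ones. The 3 genes lower in sustained MMC were all among the 238 lower after the pulse, against 0.166 for independent lists. Both lists come from the same fit with a shared spread for each gene. They are therefore not independent, and the overlap decides nothing.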

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

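The tests on the shared offset, the mismatched genes, the array clusters, the compressed range and time in culture were chosen only after the result was seen. Outliers were searched for in 41 groups of values, and 4 were found, where chance alone gives about 1 in 20.

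The before array of unexposed 2 had a median correlation of 0.626 with the other before arrays, which themselves had medians of 0.895 to 0.938. Genes placed on the wrong probes would leave neighbours uncorrelated, yet the changes of chromosomal neighbours in unexposed 2 correlated at 0.314. A growth state as the whole cause is argued against by the deviation of its before array from the others, which correlated between neighbours at only 0.0670, where levels on the other before arrays did at 0.160. The deviations of its before and after arrays correlated at 0.982, but this follows from the correlation of 0.985 between these arrays and decides nothing. A probe offset shared by both arrays, from the array lot or the labelling, stays open, as does a difference between cultures in part.

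Ribosomal protein genes had medians of -2.05, -0.96 and -1.93 in sustained 2, pulse 1 and pulse 2, and of -0.32 and -0.30 in sustained 1a and 3. A fall of bright probes as a class is argued against, because in those 3 experiments the ribosomal median lay at percentile 0 of 10000 lists matched on intensity. A compressed range of levels on the sustained 3 arrays is argued against too. There the SD of deposited log2 values over the ribosomal probes was at least 1.03 times the median SD on the other experiments' arrays. Those arrays ran from 0.842 to 1.45 times. That SD does not measure changes, so smaller changes of bright probes as a class in sustained 3 stay open. In sustained 3 the ribosomal median was 0.146 of that in sustained 2. The 58 other probes of that brightness that changed by over 1 in sustained 2 had a median of 0.248 of that change. Their choice by the change in sustained 2 can by itself lower that ratio. The array clusters cannot be told apart from a difference between cultures. The before arrays of sustained 2, pulse 1 and pulse 2 (3 of 3) lie outside the cluster of unexposed 1, sustained 1a and sustained 3. However, sustained 1b, grouped with those 3, had a ribosomal median of only -0.37 (10 to 25 min). Its before array correlated at 0.934 to 0.948 with those of cluster A and at 0.915 to 0.966 with the others of cluster B. Its place in a cluster is thus uncertain, and its median decides nothing about the array clusters. The length of exposure differs between these experiments, growth phase may differ too, and neither was tested. In sustained MMC the ribosomal median did not follow the time. It was -0.32 at 25 min, -2.05 at 40 min and -0.30 at 80 min, each in a different experiment.

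Changes with and without MMC ran together across genes. A between-array normalization or intensity trend is argued against, since the correlation of unexposed with sustained changes was 0.579 with no normalization, 0.588 with loess and 0.612 with the offset (median scaling cannot alter it). The 100 genes that rose and the 100 that fell most without MMC moved apart by over 0.2 in 5 of 5 exposed experiments, which restates that correlation and decides nothing. Time in culture stays open, as does any other cause that cultures with and without MMC share.

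Chance was weighed by splitting the arrays of a comparison in other ways. For all exposed experiments, 2 of 100 splits drawn of 126, the real one included, gave at least the real count of 469 genes. Most of these splits leave some before and after pairs unparted. The highest other count, 666, came from a split that parted before from after in sustained 2, pulse 1 and pulse 2 only. Those are the cluster B experiments, with 659 genes when fitted as a group of their own. Among the 14 splits drawn that parted all 5 pairs, the highest other count was 1, and they are too few for a share under 0.05. For sustained MMC, 3 of 10 splits, the real one included, gave at least the real count of 3 genes. The splits are too few for a share under 0.05. The highest other count, 153, was that of splits parting sustained 2 alone, which points to a structure of the samples in which that experiment stands apart.

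The NADH dehydrogenase I median was 1.08 in sustained 2, above the other exposed experiments of the main comparisons (0.38 to 0.55). In sustained 1b it was 0.27. The chromosome replication median was -0.31 in pulse 1, below the other exposed experiments of the main comparisons (-0.10 to -0.06), with 0.009 in sustained 1b. The base excision, alkylation and mismatch repair median was -0.0566 in sustained 1a, below the other exposed experiments of the main comparisons (0.09 to 0.15). Sustained 1b, also early in MMC, had -0.003. Pyrimidine synthesis medians were below 0 in every sustained experiment and above 0 in both unexposed ones, with a median difference of -0.24 (camera adjusted p = 0.0108, adjusted p = 0.616 with an estimated correlation, and adjusted p = 0.0672 with no normalization), or -0.15 under median scaling and -0.12 with the offset. ATP synthase medians were below 0 in both pulse experiments and above 0 in both unexposed ones, with a median difference of -0.60 (camera adjusted p = 8.50e-05, and adjusted p = 0.776 with an estimated correlation) that turned to 0.30 with no normalization. Set against the other genes in that setting, the list was still called lower (camera adjusted p = 0.0025).

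In sustained 1b, which the main comparisons did not use, SOS changes between 10 and 25 min of MMC were set beside the unexposed ones, without a test. Of 13 SOS genes, sulA, umuC, umuD and dinI were left out because they were at the lowest value before in unexposed 1. Of the remaining 9, the change was above 0 and above that in either unexposed experiment for 4, with log2 changes of 0.70 for recN, 0.31 for uvrA, 0.26 for recA and 0.19 for uvrD. For yebG, uvrB and ssb the change was -0.42, -0.22 and -0.032, below that in either unexposed experiment.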

How the results depend on the processing

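The variance trend on mean intensity, the array cluster as a term, the list tests without the block or with 1 value per gene and the omission of genes at the lowest value were chosen after the result was seen. The planned trended model takes the mean change as its covariate; it ended nearly all calls, and the trend on mean intensity was tried after that. Under settings not named here the counts stayed within 1.5 times. Signal near the lowest value limits dim genes. Beyond the cases where fewer experiments were fitted, the cause was not tested. Leaving out a single experiment of a pair leaves a lone sample assumed to vary like the other groups.

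The sustained MMC change passed 3 genes. The count was 1 under median scaling, 0 with no normalization, 5 with loess, 0 with the offset, 11 with sustained 1b added, 0 with the trended robust variance, 11 with the trend on mean intensity and 0 with the unmoderated test, and 0 to 26 with an experiment left out. The pulse MMC change passed 379: 606 under median scaling, 1 with no normalization, 1 with the trended robust variance, 2 with the unmoderated test, and 0 to 584 with an experiment left out. The all MMC change passed 469: 1 with no normalization, 0 with the trended robust variance, 0 with the unmoderated test, and 33 to 540 with an experiment left out. Where 0 genes passed, pulse minus unexposed gave 1 with the trended robust variance and 1 with the trend on mean intensity, sustained minus unexposed gave 1 with the cluster term and 0 to 1 with an experiment left out, and the unexposed change 0 to 1.

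The experiment pairs the arrays (the block). With no replicate block, the sustained MMC change, pulse MMC change and all MMC change passed 0, 0 and 0 genes (65, 175 and 266 at an unadjusted p under 0.05). Of the named changes, 55 no longer passed and 35 stayed on their side of the threshold. List calls by camera went from 9 to 8 for sustained MMC, 9 to 8 for the pulse and 10 to 11 for all MMC, with the direction kept throughout. With 1 value per gene, 2 list calls changed, those of heat shock and branched-chain amino acid synthesis in the pulse (adjusted p = 0.0507 for each list, from 0.0465 and 0.041). Both calls, of lower medians (-0.18 and -0.23), also ended under median scaling (camera adjusted p = 0.257 and 0.079). They ended without the block as well (camera adjusted p = 0.142 and 0.0561).

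The median change of all genes was at most 0.06 after quantile normalization, used elsewhere, and 0.12 under median scaling (both in pulse 2), and with no normalization it was -3.00 in sustained 3 and 1.86 in pulse 1. In sustained MMC the SOS median, 0.16, was 0.08 with the offset and 0.11 with sustained 1b added, and with no normalization it turned to -0.97. There umuC was -1.08, dinI -0.46, uvrA -0.79, uvrB -0.78, ruvA -0.84, yebG -0.95 and ssb -1.02; in the pulse uvrD was 0.316 and ssb 0.083; in all MMC umuC was -0.28, uvrA -0.12, uvrB -0.22 and ruvA -0.13. Under median scaling lexA was 0.011 in sustained and 0.07 in all MMC, uvrB -0.054 in the pulse and umuD 0.10 in all MMC. With loess uvrB was -0.066 in the pulse and lexA 0.001 in all MMC. With sustained 1b added lexA was 0.035 in sustained and 0.041 in all MMC. With an experiment left out, lexA was -0.19 to 0.025 in sustained, -0.127 to 0.236 in the pulse and -0.068 to 0.04 in all MMC, and umuD -0.206 to 0.078 in all MMC. In sustained MMC umuC was then -0.214 to 0.32 and uvrD -0.23 to 0.045, and in the pulse uvrA -0.053 to 0.372 and uvrB 0 to 0.094. None of these changes had passed the test.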

Other observations

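The tna operon encodes tryptophanase, its leader peptide and a tryptophan permease. Its genes had large changes in experiments with and without MMC, except in those sampled at 25 min. None of them passed the test in the unexposed experiments, and tnaA was chosen after its values were seen. On the log2 scale tnaA changed by 3.42 and 3.30 in unexposed 1 and 2, by 6.43 and 5.99 in sustained 2 and 3, and by 4.13 and 6.25 in pulse 1 and 2. At 25 min, in sustained 1a, its change was -0.10. Over all exposed experiments tnaC rose by 2.51 ± 0.453 (n = 5; limma adjusted p = 0.0187), with tnaC at the lowest array value on 2 of 5 before arrays. In unexposed 1 and 2 its changes were 1.92 and 3.32.

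Further genes outside the lists rose or fell over the 5 exposed experiments. The sorbitol transport gene srlE rose by 1.84 ± 0.462 (3.58-fold) and gcvH, of the glycine cleavage system, 3.99-fold (limma adjusted p = 0.0388 and 0.0224). For srlE, at the lowest value on 1 of 5 before arrays, the change was 0.49 in unexposed 2 and at least 1.83 in unexposed 1, where it was at the lowest value before. For gcvH the changes in unexposed 1 and 2 were 1.65 and 2.64. The aldehyde reductase gene dkgB fell by 1.55 ± 0.228 (limma adjusted p = 0.0107), with dkgB at the lowest value on 1 of 5 after arrays, and in the unexposed experiments its changes were -0.23 and -0.44.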
